A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

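Gene expression was measured on 4 spotted 2-colour arrays, 2 for the wild type and 2 for the ptc1 strain. Per the labels' protocols, cultures grown at 28 °C in rich medium were treated at an absorbance (A660) of 0.5 with rapamycin at 200 ng/ml for 1 h, total RNA was purified with a column kit, and cDNA from 8 µg of it was labelled indirectly with Cy3 or Cy5. Mock treatment used the ethanol and Tween-20 vehicle. Per the labels a dye swap was made for each RNA sample, so the arrays of a strain were taken as repeats of 1 RNA pair and counted as 1 biological sample. Separate cultures for the arrays are not ruled out by the sources used here. On this reading the SD over 2 arrays of a strain carries technical spread alone.

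Per the labels, the authors left out spots with a diameter under 120 µm or with Cy3 and Cy5 intensities under 150 units and normalised by the ratio of medians. The deposited table then holds a log ratio for each open reading frame and array, taken here as log2, with 6212 rows and 3 decimals. Scanner software, background correction, treatment of repeated spots and the base of the logarithm are not given in the sources used here. Were the base another, every fold, the 2-fold rule and the genes picked for relative sizes would change, while signs, correlations and percentiles of list medians would not. The direction is not stated with the values either. It was taken as rapamycin over mock because the study's design names treated cells against mock-treated cells, and it is likely on the further ground that GAP1 and other nitrogen-repressed genes, long known to respond to rapamycin with increased expression, carry positive values. All 4 columns correlated positively with each other (r from 0.869 to 0.958 across genes), so the deposited values already run in the same direction although the dyes were swapped, and no sign was turned. For the ptc1 arrays the titles and the dye fields of the labels name opposite dyes. This does not alter the means of the strains, which hold both orientations. The medians of the columns were 0.131 and −0.0015 in the wild type and 0.015 and 0.083 in ptc1, so centring of all values at 0 was not exact, and centring wild-type array 1 on its median moves all its values by 0.131. Intensities were not used here, so gene lists could not be matched on expression level, and the number of arrays limits the precision.

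Rows were named through a table of the R64 assembly of the S288C reference strain, used for names and for the order of genes along chromosomes. By locus tag 5662 rows matched and by a unique synonym 52, and 498 kept the identifier of the file. Averaging rows of the same gene removed 36 rows and left 6176 genes, of which 584 had no value on any array. The rules, lists and comparisons were fixed before the data were examined. With 1 RNA pair per strain no test was run. A gene counted as changed in a strain when it was measured on both arrays, its mean log2 ratio was at least 1 in size and both arrays had the same sign. It counted as differing between strains when it was measured on all 4 arrays, the ptc1 mean minus the wild-type mean was at least 1 in size and all 4 array-to-array differences had the same sign. The ± of a difference is the square root of the summed squares of the SDs of the strains. As a level for the rules with no treatment or strain effect, the sign of an array was turned within a strain, and arrays were paired across strains. These contrasts can still hold a dye effect. A turned sign makes genes with like values on both arrays fail the condition on signs, so the count with no such condition is given. The relative size of the ptc1 response used genes picked at 2-fold on a wild-type array and read on the other wild-type array and in ptc1, both ways round.

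Each of 29 gene lists, written from general knowledge of yeast, was described by its median, by its members past the rule and by the percentile of its median among 10000 random lists of the same size. For the strain difference a further 10000 lists were drawn from the same 10 bins of the wild-type mean, list members included. The lists cover ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, translation, nitrogen catabolite repression, retrograde response, TCA cycle, respiration, general stress, storage carbohydrates, autophagy, vacuolar proteases, proteasome, cell wall integrity, amino acid and sulfur amino acid synthesis, glycolysis, hexose transport, fatty acid oxidation, the phosphate regulon, heat shock, ergosterol, histones, G1 and S phase, TOR-linked regulators, type 2C phosphatases, mating, meiosis and housekeeping genes. Some share members: the stress list shares 13 genes with storage carbohydrates, 6 with heat shock and 2 each with the nitrogen and vacuolar lists, and the nitrogen list shares 3 with vacuolar proteases. ECI1 and ATP18 were not matched. Named genes were, by a rule fixed in advance, PTC1, the 10 largest rises and falls of each strain, the 10 highest and lowest strain differences, and per list up to 4 members by size of the wild-type mean and up to 4 by size of the difference. Other genes named where a count was 5 or fewer or where a list's calls are given in full (RPL31B, RPL41A, NOP1, LEU1, PRO1, BAT1, ILV5, ARG3, ENP1, RRB1, UTP4 and PDC6 in the results, and further ones in the closing section) were chosen after their values were seen.

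Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9. The rules were tested on simulated data of 4650 genes with the array spread of each comparison. At a planted log2 change of 1.5 the rule passed 100% of genes for the wild type, 92% for ptc1 and 94% for the strain difference, at 0.5 it passed 2%, 4% and 8%, and of unchanged genes 0.02%, 0.02% and 0.34%. A relative size made as 1 was returned as 0.983 for rises and 1.02 for falls, and a size made as 0.8 as 0.806 and 0.831. Of 100 lists of 30 genes drawn at random from the measured values, 7% had a median strain difference outside the central 95% of random lists. This checks the percentile for random lists only, not for genes that vary together. Alternatives were thresholds of 1.5-fold and 3-fold, every array past the threshold, no condition on signs, centring, scaling of arrays to equal spread, other rules on missing values, medians of repeated rows, list means and the removal of each array in turn. Counting only features matched to the reference, and matching each list member to the 50 nearest genes by wild-type mean outside its list, were added after seeing the data.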

Results

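The transcriptional response of budding yeast, Saccharomyces cerevisiae, to rapamycin was measured in a wild-type strain and in a ptc1 strain, which lacks the Ptc1 protein phosphatase. Rapamycin inhibits TORC1, the kinase complex that couples growth to nutrient supply. Cells growing in rich medium were exposed to 200 ng/ml rapamycin for 1 h or were mock-treated with the vehicle, and each 2-colour array compared treated with mock-treated cells of the same strain. There were 4 arrays, 2 per strain, and the arrays of a strain were taken as a dye swap of 1 pair of RNA samples, without replicate cultures. The ± of a mean in a strain is the SD of its 2 arrays, that of a strain difference combines the SDs of both strains, and no p-value was calculated. Values are log2 ratios read as rapamycin over mock, although neither the log base nor the direction was stated with them. A gene is said to have risen or fallen where its mean log2 ratio was at least 1 in size, which is 2-fold, with the same sign on both arrays of the strain.

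Of 6212 rows, 5017 and 5006 had a value on the wild-type arrays 1 and 2, and 5418 and 5301 on the ptc1 arrays 1 and 2. After rows of the same gene were averaged, 4796 genes were measured on both wild-type arrays, 5221 on both ptc1 arrays and 4650 on all 4, and the number of arrays limits the precision. Across those 4650 genes, which are not independent replicates, the arrays of a pair correlated with Pearson's r = 0.958 in the wild type and r = 0.869 in ptc1. The median SD of the 2 arrays of a gene was 0.155 in the wild type and 0.277 in ptc1, so the ptc1 values were the less precise. PTC1 itself (YDL006W) had log2 ratios of 0.003 and −0.525 on the wild-type arrays, a mean of −0.26 ± 0.37 that is within the array spread. It had no value on either ptc1 array.

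The first comparison asked which genes respond to rapamycin in wild-type cells. In these cells 660 genes rose (13.8% of those measured) and 718 fell (15.0%). With the sign of an array turned, which removes the treatment effect from the mean and leaves the dye effect, and with no condition on signs, 1 gene was past the same size. GAP1 (YKR039W), the general amino acid permease, rose most, by 5.60 ± 0.09 or 48.6-fold. COS4, a member of a subtelomeric family of similar genes, followed with 5.53 ± 0.49, and TMT1, which encodes trans-aconitate methyltransferase, with 4.93 ± 0.15. HOS4 (4.89 ± 0.34), HSP12 (4.88 ± 0.10), ARO5 (4.78 ± 0.20), CPS1 (4.72 ± 0.61), ARG4 (4.59 ± 0.02), SNZ1 (4.58 ± 0.04) and DDR2 (4.42 ± 0.26) completed the 10 largest rises. Of the 10 deepest falls 7 were in ribosomal protein genes, led by RPS22A (−5.33 ± 0.23, 40.1-fold lower), RPS9B (−5.02 ± 0.26) and RPL9A (−4.96 ± 0.08). The pyrimidine synthesis genes URA7 (−4.95 ± 0.10) and URA1 (−4.81 ± 0.20) and the RNA polymerase I subunit gene RPA43 (−4.54 ± 0.11) were the others.

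Genes for making ribosomes fell together in the wild type. Of 117 measured cytosolic ribosomal protein genes 116 fell, with a list median of −3.68, and the exception was RPL31B at −0.38. Many of these genes exist as near-identical pairs that an array may not separate, so their single values are uncertain. Of 85 measured ribosome biogenesis genes 68 fell, with a median of −2.62, among them NOP56 (−4.17 ± 0.12), NOG2 (−3.98 ± 0.20), NUG1 (−3.97 ± 0.14) and UTP13 (−3.92 ± 0.09). NOP1 (YDL014W), the gene for the nucleolar protein fibrillarin, was the only member that rose, by 1.22. The RNA polymerase I and III subunit list had 13 of 19 members lower (median −1.48), including RPA135 (−3.21 ± 0.08) and RPA34 (−3.12 ± 0.13). Translation factors and tRNA synthetases had 31 of 49 lower (median −1.29), including TEF4 (−2.53 ± 0.09), PRT1 (−2.46 ± 0.02) and TIF4631 (−2.30 ± 0.06). None of 10000 random lists of the same size had a median as low as any of these lists.

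Nitrogen catabolite repression targets, which take up and break down poor nitrogen sources, rose in 23 of 30 measured members (median 2.20). Next to GAP1 and the vacuolar carboxypeptidase gene CPS1 they included the ammonium permease gene MEP2 (4.00 ± 0.16) and DAL3 of allantoin breakdown (3.81 ± 0.17). Of 10 retrograde response targets 7 rose (median 1.57), led by the peroxisomal citrate synthase gene CIT2 (4.12 ± 0.09) and the pyruvate carboxylase gene PYC1 (3.34 ± 0.29). In the TCA cycle list 5 of 15 rose (median 0.58), with IDP1 at 2.38 ± 0.43 and SDH4 at 1.90 ± 0.39. In the respiratory chain and ATP synthase list 6 of 29 rose and NDE1 fell (−1.17 ± 0.17), the median being 0.70, and COX5B showed the largest value (2.96 ± 0.19). The amino acid biosynthesis list, targets of the activator Gcn4, was mixed. It had 21 of 49 members higher and 4 lower, with a median of 0.82. The arginine pathway genes ARG4, ARG1 (3.98 ± 0.23) and CPA1 (3.26 ± 0.17) were among its largest rises, and the 4 that fell were LEU1 (−2.13), PRO1 (−1.87), BAT1 (−1.60) and ILV5 (−1.54).

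General stress genes, targets of the activators Msn2 and Msn4, rose in 43 of 52 measured members (median 1.78), with HSP26 at 4.36 ± 0.05 and the vacuolar aminopeptidase gene APE1 at 4.29 ± 0.08 beside HSP12 and DDR2. The storage carbohydrate list shares 13 genes with the stress list. In it 10 of 18 rose (median 1.04), including GLC3 of glycogen synthesis (3.18 ± 0.32) and GDB1 of glycogen breakdown (2.66 ± 0.36). All 9 measured vacuolar protease genes rose (median 1.82), including PRB1 (2.64 ± 0.05) and the inhibitor gene PBI2 (2.48 ± 0.37). Of 28 autophagy genes 11 rose (median 0.58), among them ATG8, whose product builds the autophagosome membrane (3.69 ± 0.13), and AMS1 (3.40 ± 0.08), and ATG22 fell (−1.65 ± 0.33). Cell wall integrity genes, controlled by the kinase Slt2 and the factor Rlm1, rose in 15 of 28 members (median 1.18), including SRL3 (3.58 ± 0.06), PRM5 (2.82, with an SD that rounds to 0.00) and KDX1 (2.74 ± 0.37). In the heat shock chaperone list 8 of 24 rose and MGE1 fell (−1.37 ± 0.47), with a median of 0.67. The medians of the nitrogen, retrograde, stress, storage, vacuolar, cell wall and amino acid lists lay above all 10000 random lists of their size. Those of the TCA cycle (percentile 97.9), respiratory (99.9), autophagy (99.8) and heat shock (99.8) lists lay in the top 2.5%.

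**Figure D1:**
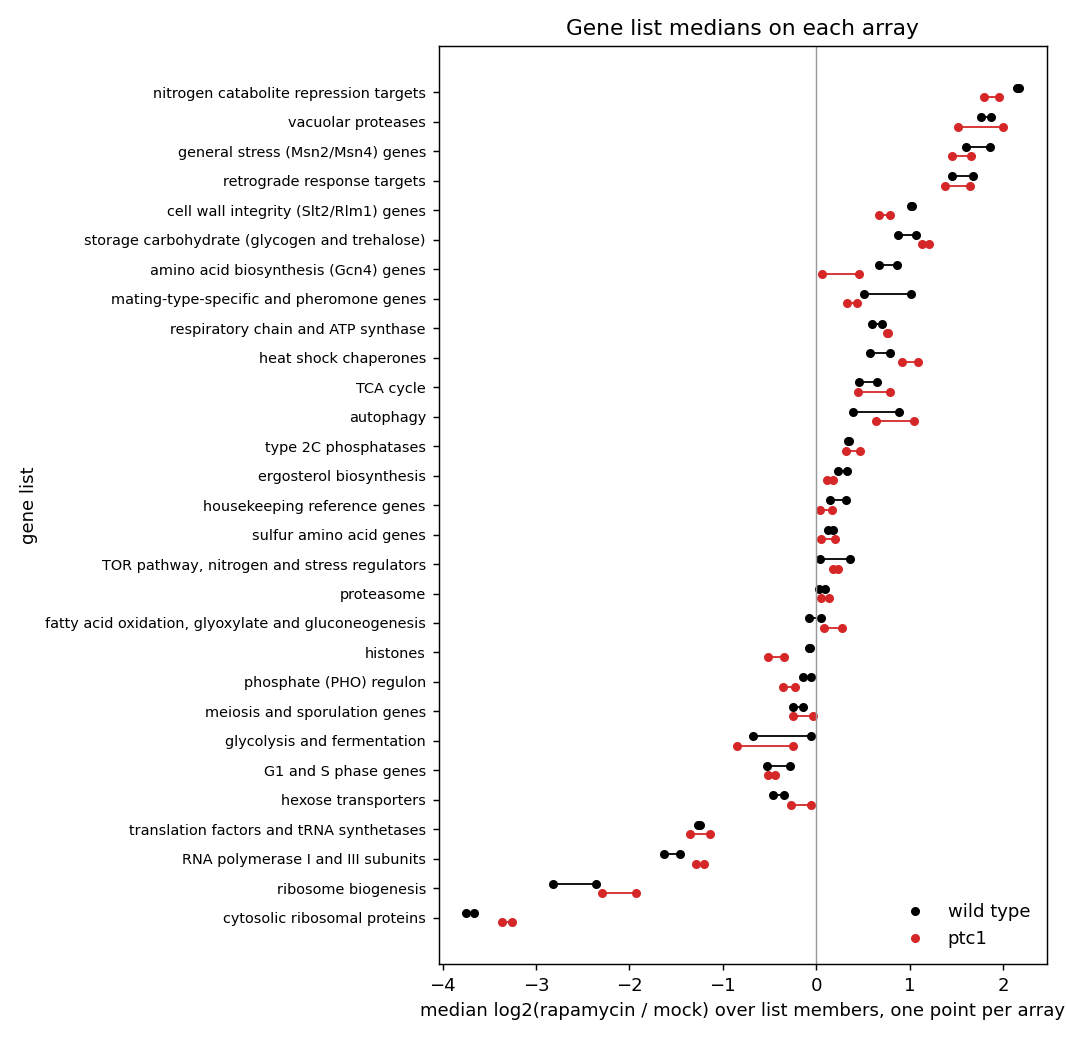
Median log2(rapamycin/mock) of each of the 29 gene lists over members measured on both arrays of the strain, with a black point per wild-type array and a red point per ptc1 array and a line joining the arrays of a strain. Ribosomal protein genes lie lowest (wild-type median −3.68) and nitrogen catabolite repression targets highest (2.20). The amino acid and cell wall integrity lists are lower on both ptc1 arrays than on both wild-type arrays. So are the nitrogen, mating, histone, phosphate and ergosterol lists.

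The second comparison asked the same of cells without Ptc1. In ptc1, 551 genes rose (10.6% of those measured) and 647 fell (12.4%), and with the sign of an array turned and no condition on signs 3 genes were past the same size. The 10 largest rises were those of GAP1 (4.77 ± 0.69), MEP2 (4.26 ± 0.22), HOS4 (4.25 ± 0.68), the allantoate permease gene DAL5 (3.99 ± 0.36), the carnitine acetyltransferase gene YAT2 (3.79 ± 0.58), DAL3 (3.69 ± 0.56), SNZ1 (3.64 ± 0.19), GPG1 (3.63 ± 0.17), CPS1 (3.56 ± 0.26) and NQM1 (3.45 ± 0.19). The deepest falls were again those of RPS22A (−4.79 ± 0.27), RPL9A (−4.56 ± 0.36), RPS9B (−4.54 ± 0.32) and URA7 (−4.36 ± 0.29), followed by RPL5, RPS7A, URA1, RPL2A, RPL2B and RPS16B between −4.23 and −3.94. Of 125 measured ribosomal protein genes 123 fell (median −3.40), the exceptions being RPL31B (−0.23) and RPL41A (−0.93), and 68 of 87 ribosome biogenesis genes fell (median −2.18). RNA polymerase I and III subunits (13 of 21, median −1.26) and translation factors and tRNA synthetases (36 of 52, median −1.25) fell too, and none of 10000 random lists of the same size had medians as low.

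Among the lists that rose in the wild type, nitrogen catabolite repression targets had 27 of 35 members higher in ptc1 (median 1.79), retrograde targets 7 of 9 (median 1.78), general stress genes 42 of 54 (median 1.52), storage carbohydrate genes 11 of 21 (median 1.17), vacuolar proteases 7 of 9 (median 1.79) and autophagy genes 12 of 29 (median 0.81). The TCA cycle list had 4 of 16 higher (median 0.72) and the respiratory list 7 of 30 (median 0.75). Cell wall integrity genes had 11 of 31 higher (median 0.82) and heat shock chaperones 13 of 24 (median 1.01). Against random lists of the same size these 10 medians lay at percentile 100, save that of the TCA cycle at 99.9. They cover the genes measured in ptc1, for most lists not the same set as in the wild type. Over genes measured on all 4 arrays the wild-type and ptc1 medians were 1.76 and 1.78 for retrograde targets. They were 1.04 and 1.01 for storage carbohydrates and 0.58 and 0.77 for autophagy. The amino acid list had 14 of 51 members higher and 7 lower, and its median of 0.21 lay at percentile 87.7 of random lists, inside their central 95%.

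The third comparison asked whether the response depends on Ptc1. The strain means correlated across the 4650 shared genes with r = 0.960 and Spearman's rho = 0.932. Of the 643 shared genes that rose in the wild type 440 also rose in ptc1 (68.4%), where independent lists would share 70.7, and of the 697 that fell 542 fell in ptc1 (77.8%), where independent lists would share 86.9. The number of genes past the rule in opposite directions was 0. Genes picked on a wild-type array at 2-fold were then read on the other wild-type array and in ptc1. The median rise was 1.40 ± 0.13 in the wild type and 1.18 ± 0.08 in ptc1, and the median fall −1.80 ± 0.07 and −1.51 ± 0.01, the ± being the SD over the 2 ways of picking. The ptc1 response was thus 0.842 ± 0.020 of the wild-type size for rises and 0.839 ± 0.024 for falls. Genes picked at 3-fold gave 0.787 ± 0.002 for rises and 0.871 ± 0.028 for falls.

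**Figure D2:**
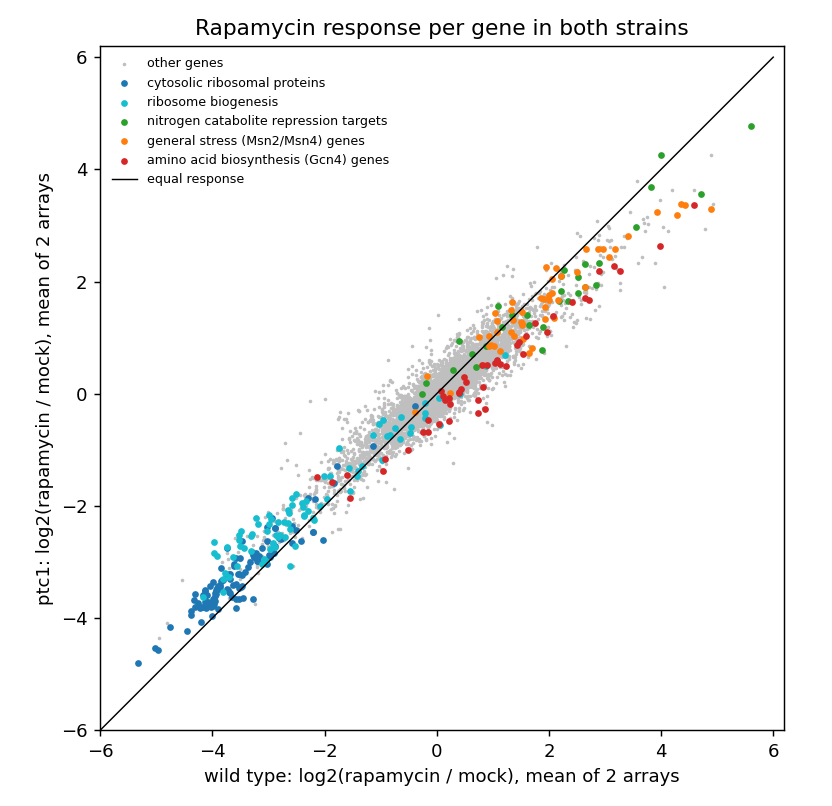
Mean log2(rapamycin/mock) over 2 arrays in the wild type (x axis) and in ptc1 (y axis), a point per gene measured on all 4 arrays, with 5 gene lists in colour and a line of equal response. Points follow the line (r = 0.960), and those of the amino acid biosynthesis list lie mostly below it, with 45 of 48 members lower in ptc1.

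A strain difference was called where the ptc1 mean minus the wild-type mean was at least 1 in size and all 4 differences between a ptc1 and a wild-type array had the same sign. It held for 89 genes (1.91%), 46 with a higher and 43 with a lower ratio in ptc1. Other pairings of the arrays set 1 array of each strain on either side. They gave 8 genes when split by array number and 32 when split by dye as in the dye fields. With arrays scaled to equal spread the strains differed in 63 genes and these pairings in 6 and 39. If the dye fields are right, the split by dye holds any dye effect, whereas each strain mean holds both dye orientations. Its counts then do not measure how many strain calls come from array spread. If the titles are right, this split balances the dyes and its counts reflect array spread. In simulated data with this array spread 0.34% of unchanged genes passed the rule, so some calls can arise without a strain effect. The SD over genes was 0.367 for the strain difference, which holds the spread of both strains. With the sign of an array turned it was 0.181 in the wild type and 0.287 in ptc1, dye effect included. Single calls remain uncertain. In 80 of the 89 the ptc1 value was closer to 0, whatever its sign. These include genes such as CSR2 whose sign was opposite in ptc1, as it was on all arrays for 9 of the 89. Of the 43 lower genes 35 had risen in the wild type, and of the 46 higher genes 32 had fallen there. Where responses are smaller in ptc1 in general, a fixed size of difference favours genes with large wild-type responses. These shares can therefore restate the smaller ptc1 response in part. The call counts rest on the arrays used. Without wild-type array 2, 73 genes were lower, without ptc1 array 1, 90 were higher and 113 lower, and without ptc1 array 2, 81 were lower. Because each value is a ratio to mock-treated cells of the same strain, a difference can lie in the treated or in the mock-treated cells.

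ARO10 (YDR380W), which encodes phenylpyruvate decarboxylase, had the largest decrease in response, from 4.05 ± 0.06 in the wild type to 1.90 ± 0.99 in ptc1, a difference of −2.15 ± 0.99. ARO5 (YGL117W) went from 4.78 to 2.93 (difference −1.84 ± 0.20), HSP12 (YFL014W) from 4.88 to 3.29 (−1.59 ± 0.48), the peroxiredoxin gene TSA2 (YDR453C) from 3.89 to 2.33 (−1.56 ± 0.59) and TMT1 (YER175C) from 4.93 to 3.38 (−1.55 ± 0.44). The hexose transporter gene HXT6 (−1.45 ± 0.89), YIL165C (−1.42 ± 0.30) and KDX1 (−1.41 ± 0.52) had risen in the wild type, while the unnamed features YHR095W (−1.55 ± 0.48) and YGR069W (−1.41 ± 0.38) had not passed the rule there. HXT6 has a near-identical neighbour, so its value is uncertain.

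In the other direction, the galactose permease gene GAL2 (YLR081W) fell to −2.25 ± 0.06 in the wild type and stood at −0.13 ± 0.28 in ptc1, a difference of 2.13 ± 0.29. DSF1 (YEL070W) differed by 1.89 ± 0.32, the dihydroxyacetone kinase gene DAK2 (YFL053W) by 1.83 ± 0.46, the unnamed feature YLR465C by 1.74 ± 0.48 and the alcohol acetyltransferase gene ATF2 by 1.45 ± 0.80, and all of these had fallen in the wild type. The S-methylmethionine permease gene MMP1 fell to −2.67 ± 0.24 in the wild type and to −1.18 ± 0.58 in ptc1. The isomaltase gene IMA4 (1.39 ± 0.30) and NOG2 (1.34 ± 0.26), the gene of a GTPase needed for the large ribosomal subunit, had also fallen there. CSR2 (1.46 ± 0.25) and COS111 (1.37 ± 0.48) had not passed the rule in the wild type, and COS111 rose in ptc1 (1.40 ± 0.10). DSF1, DAK2, MMP1 and IMA4 lie within 20 genes of a chromosome end, and IMA4 has close copies elsewhere, so its value is uncertain.

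**Figure D3:**
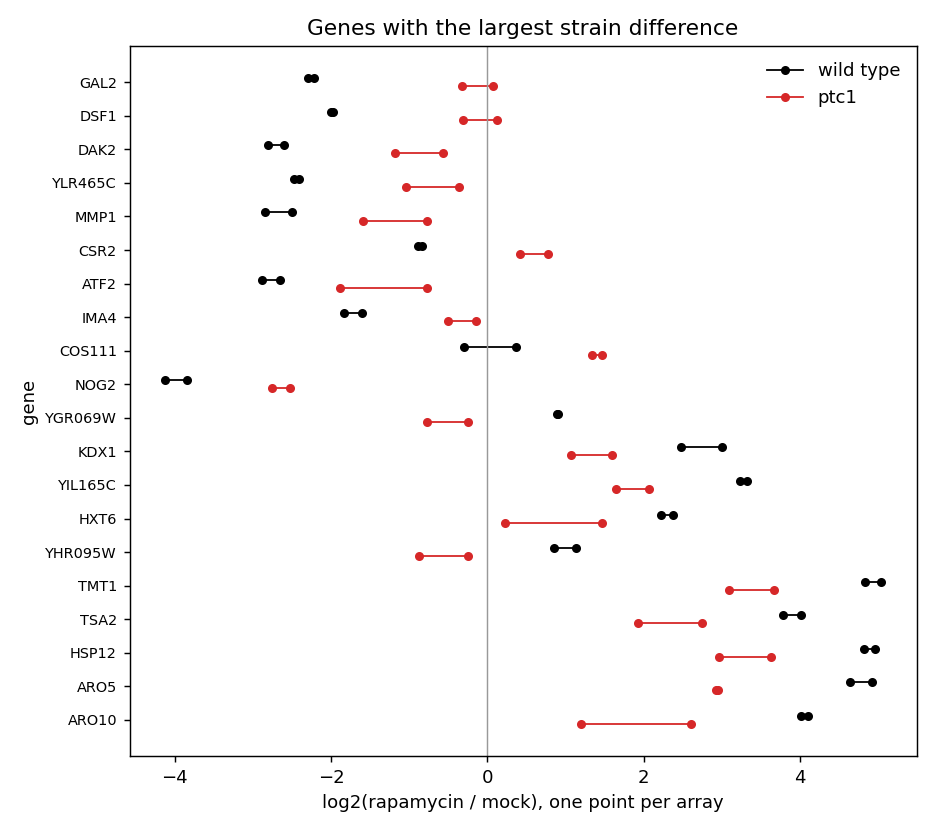
log2(rapamycin/mock) on each array (x axis; black wild type, red ptc1, a line joining the 2 arrays of a strain) for the 10 genes with the highest and the 10 with the lowest difference in response. The wild-type points of GAL2 (mean −2.25) lie below its ptc1 points (mean −0.13), and those of ARO10 (mean 4.05) above its ptc1 points (mean 1.90), whose arrays differ more from each other than those of the wild type.

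Among the gene lists, amino acid biosynthesis and cell wall integrity genes had the largest decreases in response in ptc1. Of 48 amino acid genes measured on all 4 arrays 45 had a lower ratio in ptc1, with a median difference of −0.50 that ranged from −0.76 to −0.33 over the 4 pairs of arrays. ARG1 (−1.35 ± 1.10), ARG4 (−1.22 ± 0.32), the homocitrate synthase genes LYS21 (−1.15 ± 0.60) and LYS20 (−1.09 ± 0.63), CPA1 (−1.08 ± 0.22) and ARG3 (−1.04 ± 0.41) passed the rule. LYS21 and LYS20 had parallel values over the 4 arrays, and signal shared between these genes of the same enzyme was not examined. Of 27 cell wall integrity genes 24 were lower, with a median difference of −0.49 (−0.75 to −0.21 over the 4 pairs). KDX1, PRM5 (−1.33 ± 0.05) and SRL3 (−1.24 ± 0.17) passed the rule, and SLT2, the gene of the pathway's kinase, went from 2.27 ± 0.33 to 1.31 ± 0.03, a difference of −0.96 ± 0.33 that did not. Among 10000 random lists drawn from the same bins of the wild-type mean the amino acid median lay at percentile 0 and the cell wall median at percentile 0.01. Such percentiles did not set these lists apart. Of the 29 lists 13 lay outside the central 95% of matched lists, among them glycolysis (percentile 0) and histones (0.05), whose differences were not stable over the arrays.

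The heat shock chaperone list differed in the opposite direction, with a median difference of 0.22 (0.05 to 0.31 over the 4 pairs) at percentile 100 of the matched random lists. HSP30, a gene of a plasma membrane heat shock protein, was the member past the rule, at −0.13 ± 0.16 in the wild type and 1.18 ± 0.10 in ptc1. Autophagy (median difference 0.04, percentile 99.5) and the respiratory chain (0.06, percentile 99.9) also lay above matched lists, although both medians were near 0 and the autophagy value ranged from −0.16 to 0.16 over the 4 pairs. The autophagy and respiratory lists held 0 members past the rule for a difference.

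Several lists that responded in the wild type lay inside the central 95% of random lists drawn from the same 10 bins of the wild-type mean. Among them were ribosome biogenesis genes (median difference 0.31, percentile 48.4), nitrogen catabolite repression targets (−0.28, percentile 50.2), retrograde targets (−0.29, percentile 58.1), general stress genes (−0.26, percentile 79.3), vacuolar proteases (−0.35, percentile 35.0), storage carbohydrates (−0.03, percentile 91.3), the TCA cycle (−0.03, percentile 71.1) and RNA polymerase subunits (0.12, percentile 5.69), while translation factors, at 0.08 with −0.111 to 0.225 over the 4 pairs of arrays, lay below at percentile 0.26. Ribosomal protein genes (0.35) lay inside these lists as well (percentile 19.5), but the lowest bin also holds much weaker falls. Against the 50 genes outside the list nearest to each member in the wild-type mean, whose median difference was 0.54, they lay at percentile 0, a smaller strain difference than that of other genes with similar falls. This closer matching was added after the data were seen, and it moved no other list across the 95% limits. Single members passed the fixed rule for a difference. That rule is not matched on the wild-type response, so the generally smaller response of ptc1 enters their values. NOG2, NUG1 (1.12 ± 0.28), NMD3 (1.04 ± 0.59), UTP13 (1.03 ± 0.44) and 3 further biogenesis genes, ENP1 (1.02), RRB1 (1.01) and UTP4 (1.00), fell less in ptc1, as did RPA43 (1.22 ± 0.11). CIT2 (−1.22 ± 0.10), CPS1 (−1.16 ± 0.66), CAR2 (−1.10 ± 0.79), APE1 (−1.10 ± 0.68) and IDP1 (−1.01 ± 0.51) had smaller ratios in ptc1, and so had DDR2 (−1.05 ± 1.07), whose difference was within its combined SD.

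Glycolysis and fermentation genes had a median of −0.38 in the wild type (percentile 2.44 of random lists), where PYK2 alone rose (1.76 ± 0.30). Their median was −0.73 in ptc1, where PYK2 rose (1.56 ± 0.06). ADH1 (−1.12 ± 1.26), ADH2 (−1.04 ± 0.37), PDC1 (−1.02 ± 0.66) and PDC6 (−1.09) fell in ptc1. ADH1 and PDC1 stood at −0.235 and −0.555 on ptc1 array 1, so their falls rest mostly on ptc1 array 2 (−2.013 and −1.486). The median difference of −0.24 was not stable, since it ranged from −0.63 to 0.35 over the 4 pairs and was 0.002 without wild-type array 2 and 0.083 without ptc1 array 2. Histone genes had medians of −0.07 and −0.34 with 0 of 10 past the rule in either strain, and their difference of −0.25, which ranged from −0.44 to 0.06 over the 4 pairs, became 0.006 without ptc1 array 1. In the list of G1 and S phase genes CLB6 (−1.92 ± 0.27), TOS4 (−1.35 ± 0.02) and RNR1 (−1.04 ± 0.07) fell in the wild type, and these and MCD1 (−1.01) fell in ptc1. Its medians were −0.39 (percentile 1.05 of random lists) and −0.47, with a median difference of −0.09 that ranged from −0.16 to 0.04 over the 4 pairs.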

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

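For 6 named genes past the rule for a strain difference, both wild-type arrays had a sign opposite to that of both ptc1 arrays, and the difference between the strains, given as ptc1 minus wild type, was not tested because each strain had 1 RNA pair. CSR2 had a mean log2 ratio of −0.861 in the wild type and 0.598 in ptc1, a difference of 1.459. HSP30, a heat shock protein gene, had −0.13 and 1.18 (difference 1.31), ACS1, an acetyl-CoA synthetase gene, −0.439 and 0.847 (difference 1.285), and the sulfate permease gene SUL2 −0.84 and 0.223 (difference 1.062). In the opposite direction, the features YHR095W (0.994 and −0.556, difference −1.55) and YGR069W (0.896 and −0.511, difference −1.407) had no symbol in the reference table used. Over all genes past the rule for a strain difference, 9 of 89 had such opposite signs.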

How the results depend on the processing

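Counting only features matched to the reference and matching list members to the nearest genes were chosen after seeing the data, and the other alternatives before the data were examined. Of the alternative values of counts and sizes 80 stayed within 1.5 times the count or 1 SD of the size and 26 moved. At 1.5-fold, 1264 genes rose and 1138 fell in the wild type, 1158 and 1060 in ptc1, and 232 were higher and 199 lower in ptc1 than in the wild type. At 3-fold the counts were 265 and 435, 197 and 369, and 4 and 3, as a stricter size must give. With all array-to-array differences past the threshold, 11 genes were higher and 15 lower. With arrays scaled to equal spread 28 were lower, and the relative sizes of the ptc1 response were 0.898 for rises and 0.903 for falls. Selection at 3-fold gave 0.787 and 0.871, and selection on ptc1 gave 0.878 for falls. The cause of these shifts in size was not tested. Leaving out each array in turn gave 42 to 90 genes higher and 53 to 113 lower, with 73 lower without wild-type array 2, 90 and 113 without ptc1 array 1 and 81 lower without ptc1 array 2. With no condition on signs 46 were higher and 44 lower, and the cause of the shifts on leaving out an array was not tested. On leaving out each array in turn, the lists outside the central 95% of random lists for the difference numbered 8 to 15, with 9 without wild-type array 2 and 8 without ptc1 array 1. The median difference of glycolysis ranged from −0.447 to 0.083, being 0.002 without wild-type array 2 and 0.083 without ptc1 array 2, and that of histones from −0.371 without ptc1 array 2 to 0.006 without ptc1 array 1. The cause was not tested. Features matched to the reference alone gave 637 rises and 657 falls in the wild type, 540 and 589 in ptc1, and 45 genes higher and 39 lower, and the nearest genes put 14 lists outside. Of the other values, 460 list medians and 261 named genes stayed within 1 SD, while 117 and 19 moved, 70 and 14 of them toward 0, and the 3 list medians that reversed are those given for glycolysis and histones. The smaller response of ptc1 held under centring, scaling and selection at 3-fold or on ptc1. Turning the direction of the ptc1 arrays was not run because the deposited values share a direction. No paired analysis was possible because each strain had 1 RNA pair and array numbers name arrays only. Signal over background was not available here, so its limit on single genes is unknown.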

Other observations

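All tests of explanations in this part were chosen after the result was seen. Sulfur amino acid genes went both ways, with a median of 0.20 in the wild type and 0.16 in ptc1. MET28, a regulator gene of the pathway, rose (2.22 ± 0.39 in the wild type), as did MET16 and MET10 there, while the S-adenosylmethionine synthetase gene SAM1 (−2.71 ± 0.10), the methionine permease gene MUP1 (−2.06 ± 0.26), MMP1 and CYS3 fell. Of 19 fatty acid oxidation, glyoxylate and gluconeogenesis genes YAT2 (3.58 ± 0.17), the malate synthase gene MLS1 (2.44 ± 0.38), POT1 (1.67 ± 0.18) and YAT1 (1.51 ± 0.49) rose in the wild type and again in ptc1, where MLS1 was lower by 1.24 and ACS1 and FAA2 passed the rule for a higher ratio (FAA2 by 1.02). The list medians were −0.04 and 0.03, with a median difference of 0.17 at percentile 98.4 of lists matched on the wild-type response and 97.4 of unmatched ones. It ranged from −0.011 to 0.297 over the 4 pairs of arrays. In the phosphate regulon PHM8 (2.52 ± 0.05), PHO8 (1.72 ± 0.26) and GPP2 (1.64 ± 0.49) rose and CTF19, PHO89, PHO12, PHO11 and VTC3 fell in the wild type, the list medians being −0.13 and −0.31 and the median difference −0.19 at matched percentile 0.84. Among 8 measured hexose transporter genes HXT6 rose and GAL2 and HXT13 fell in the wild type, and the 13 measured in ptc1 had HXT2 lower. Medians were −0.46 and −0.13 over these different sets and −0.03 and 0.22 over the 6 genes shared, whose median difference of 0.40 (matched percentile 99.7) ranged from −0.002 to 0.618 over the 4 pairs of arrays.

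Mating genes rose in part in the wild type, with AGA2 (1.78 ± 0.37), AGA1, STE2 (1.25 ± 0.15), BAR1 (1.21 ± 0.29) and FUS1 (1.18) past the rule among 14, and AGA2 (1.01 ± 0.46) and FUS1 (1.28) in ptc1. Their medians were 0.74 (percentile 99.35 of random lists) and 0.34, and the median difference −0.19. Of 33 TOR-linked regulators GAT1 (1.33 ± 0.33), NPR1 (1.27 ± 0.28), RIM15 (1.13 ± 0.43) and YAK1 (1.03 ± 0.02) rose and SAP185 fell in the wild type, with list medians of 0.16 and 0.27 and a median difference of 0.03. Proteasome genes lay near 0 (medians 0.03 and 0.14, difference 0.10, with SCL1 lower in both strains). So did ergosterol genes (0.30 and 0.17, difference −0.16, with ERG28 higher in the wild type and ECM22 past the rule for a difference). Meiosis genes (−0.16 and −0.34, difference 0.05, with SPS100 lower in both strains) and type 2C phosphatases (0.35 and 0.39, difference 0.07, with 0 of 6 past the rule in either strain) did too. The wild-type median of the phosphatases includes PTC1 itself. Housekeeping genes, 7 measured in the wild type and 10 in ptc1, had medians of 0.20 and 0.04, and their median difference of −0.31 lay at matched percentile 0.93 and below 0 with arrays centred (−0.30) or scaled (−0.29). A low matched percentile was thus also seen for genes often taken as stable, and alone it does not tie a list to Ptc1. The actin gene ACT1 had 0.68 ± 0.16 in the wild type and 0.23 ± 0.26 in ptc1, and PDA1 rose in the wild type (1.00 ± 0.12).

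Responses were smaller in ptc1, and a uniformly narrower scale of the ptc1 arrays was considered. For genes picked at 2-fold the relative sizes of rises and falls differed by 0.003 against a summed spread of 0.044, as a uniform scale requires. A strain that responds less by a constant factor predicts the same, so this comparison cannot tell the arrays from the strain. For genes picked at 3-fold they differed by 0.084 against 0.031. That spread comes from only 2 selections. Arrays simulated with a uniform size of 0.8 and picked at 2-fold also returned unequal sizes, 0.806 for rises and 0.831 for falls. The gap at 3-fold therefore does not decide for or against a uniform scale. For the list differences, scaling to equal spread takes out a narrower scale only in part. It left relative sizes of 0.898 for rises and 0.903 for falls. After scaling to equal spread the median difference was −0.463 (−0.78 to −0.195 over the 4 pairs of arrays) for amino acid genes. For cell wall genes it was −0.4 (−0.769 to −0.052), and the pair at −0.052 is too small to decide after a partial correction. A uniform scale acts alike on genes with like wild-type responses. The 50 genes nearest to each member in the wild-type mean had median differences of −0.134 (amino acid) and −0.222 (cell wall). The unscaled medians of the lists were −0.497 and −0.488, which argues against a uniform scale as the whole of these list differences. The unscaled values nearest to 0 among the 4 pairs, which differ in dye, were −0.328 and −0.208 for these lists, which argues against a dye effect. With 1 RNA pair per strain, a difference between cultures cannot be told apart from the absence of Ptc1. A candidate explanation is therefore that cells without Ptc1 respond less in the amino acid and cell wall groups, or that mock-treated ptc1 cells already differ there, and the arrays, which hold no direct comparison of the strains, leave this open.

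Of 45 genes with a known position that were higher in ptc1, 15 lay within 20 genes of a chromosome end, where random lists matched on the wild-type response had a median of 4 and at most 13. Genes lower in ptc1 showed no such excess (5 of 39), and all 420 measured genes near an end had a median difference of −0.005, so a shift of chromosome ends as a whole is not seen. The PAU genes, a subtelomeric family of similar sequence, had a median of −1.39 in the wild type and −0.45 in ptc1, with all 17 differences between 0.51 and 1.23 and a median difference of 0.80 after centring and 0.69 after scaling. The share near an end was 33.3% where 9.48% of measured genes lie there. Gene families were then set by the shared letters of symbols near ends and not by sequence. Copies with unlike names can therefore remain, and unrelated genes with like names are left out. Without these families and unnamed genes the share was 15.4% (4 of 26) where 5.92% do, with a matched median of 1 and 618 of 10000 matched lists as high. The share thus fell and so did the number of genes, and these values do not decide between position and signal shared between near-identical copies.

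Titles and dye fields disagreed on the dyes of the ptc1 arrays. If array 1 minus array 2 reflects dye bias, the correlation of this quantity between strains across genes should be above 0 where the titles hold and below 0 where the dye fields hold. It was −0.315, which suggests that the dye fields are right. The same contrast, seen gene by gene, gave 32 genes past the rule for a difference when arrays were split by these fields and 8 when split by the titles. The means of the strains do not depend on this.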
